A study of Xenopus tropicalis with 4 samples.

How the data were processed

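Methylated DNA was captured from whole embryos of the frog Xenopus tropicalis as blastulae, at stage 9 of the Nieuwkoop-Faber series, and as gastrulae, at stage 12.5. Per the labels' protocols, embryos came from natural matings after hormone injection, and their DNA was sheared to fragments of about 500 bp. The fragments were bound to a tagged fusion protein that carries a methyl-CpG-binding domain (MBD), which the series' design text gives as that of MeCP2. After washes with 200 and 300 mM NaCl, bound DNA was eluted with 500 mM and then with 700 mM NaCl, and each eluate was sequenced as a library of its own. A methyl-CpG-binding domain holds DNA with more methylated CpG sites more tightly, so a later elution step is meant to hold DNA with denser methylation. The 4 libraries, 1 for each stage and fraction, are the whole design.

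The authors deposited 1 list of read intervals and 1 list of peaks for each library. All of them are plain coordinates on numbered scaffolds. The aligner, the peak caller, its threshold, any background sample and the genome build are not given in the sources used here. In the deposited 500 mM read lists every interval is 200 bp long, has no strand and is present once. In the deposited 700 mM read lists every interval is 300 bp long, has a strand and can be repeated. The fraction and this difference in file preparation cannot be told apart. The deposited peak lists give start and end only, with no score, height or p-value, and peaks within a list do not overlap. Each list was deposited with 1 library. Whether peaks were called on that library alone is not given in the sources used here, and both 500 mM lists hold peaks with 0 unique reads of their library.

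Reads were counted here from those intervals. An interval was placed at its midpoint, and reads with the same start and strand were counted once, which left 2676850 unique reads at stage 9 and 2531145 at stage 12.5 in 500 mM, and 3730584 and 2668634 in 700 mM. Peaks of all 4 lists were merged into 141246 regions. For each comparison of 2 libraries, a region needed at least 20 unique reads in both together. Its log2 ratio was taken on reads scaled to the total of unique reads after adding 1 read to each library. Folds printed for single regions are ratios of scaled reads with no pseudocount, with a 95% exact conditional binomial interval. A change beyond 2-fold was counted in each direction, as scaled and again after the median ratio had been subtracted. Both counts were set beside 20 seeded binomial draws in which every region had the median ratio. Peak overlap needed at least 1 shared base and was set beside 100 seeded placements of the peaks at random within their own scaffolds. Percentages of peaks and reads have exact Clopper-Pearson intervals. Intervals of percentages and folds cover counting error only, since reads without molecular identifiers are not independent molecules and neighbouring regions are not independent either. Intervals given after a median log2 ratio are 95% exact order-statistic intervals across regions. They treat regions as independent, which they are not, and hold no error between libraries.

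Each group held 1 library, so no test between stages or between fractions was made and no difference has a replicate check. A model with stage and fraction as terms, which would treat the stages as replicates of a fraction and the elutions of a capture as replicates of a stage, was not fitted. No p-value is given across regions, which are not replicates. The stage comparison was made in both fractions, which share no library. Per the labels' protocols they are successive elutions of captured DNA, so embryo batch and capture are shared by both, and their agreement is no repeat of the stage difference. Between the 2 sets of stage ratios, Spearman's and Pearson's correlation were computed across regions, and the number of regions beyond 2-fold the same way in both fractions was set beside the number that independent lists of the same lengths would share.

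The regions named in the text were chosen by a rule fixed before the data were examined. Among merged regions with at least 20 unique reads in each fraction, the rule took the 8 highest and the 8 lowest by the smaller of their 2 log2 stage ratios in absolute size, where both ratios had the same sign. It added the 3 regions per library with the most unique reads per kb, which gave 6 distinct regions. Scaffolds under 10000 bp and regions under 100 bp were left out. Other regions and scaffolds named in the closing section were chosen after their values were seen. Coordinates are counted from 1 on the scaffolds of the deposited files.

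A genome sequence and gene positions on these scaffolds were not used here. The gene table at hand belongs to the assembly UCB_Xtro_10.0 and lists genes on chromosomes, so no region could be assigned to a gene, exon or intron. The planned accounts of CpG density, of peak location in genes, of fixed gene lists and of named genes were therefore not run. Alternatives that needed a peak score were not run either.

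Alternatives fixed before the data were examined were all deposited reads, scaling to reads outside peaks, scaling by the median ratio, a pseudocount of 5 reads, minimums of 10 and 50 reads, thinning to the smallest library, windows of 2000 bp, reads placed 150 bp downstream, peaks merged within 500 bp, overlap over at least 50% of both peaks, and peaks widened by 500 bp. Others were added after the data had been seen, and the closing section names them. The overlap counts were checked against bedtools 2.31.1 and were equal in all 4 comparisons. The rule for a change in both fractions was tested on simulated data over 45071 regions, with 100 regions raised and 100 lowered in both fractions. Without a shift of the median, it recovered 10% of the raised and 19% of the lowered regions at a simulated fold of 2, 77% and 80% at a fold of 4, and 87% and 92% at a fold of 8, and called 9 to 24 unchanged regions higher and 11 to 21 lower. With the observed median shift added to every region, it recovered 50% and 3%, 91% and 57%, and 85% and 88%, and called 272 to 291 unchanged regions higher and 0 lower. Unchanged regions in this simulation varied by counting error only. Real ratios spread more, with a standard deviation of 0.78 over 55266 regions in 500 mM, against 0.51 in draws. In 700 mM it was 0.61 over 79443 regions, against 0.49. These rates therefore do not give the share of wrong calls in the real libraries. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.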

Results

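Captured methylated DNA was compared between blastula (stage 9) and gastrula (stage 12.5) embryos of Xenopus tropicalis, in DNA eluted with 500 mM and with 700 mM NaCl. Each combination of stage and fraction was 1 library, so none of the values below has a replicate error. In 500 mM, 2676850 reads were deposited for stage 9 and 2531145 for stage 12.5, all at distinct positions. In 700 mM, 3798281 reads were deposited for stage 9, of which 1.78% (95% interval 1.77 to 1.80) repeated the position and strand of another. For stage 12.5 in 700 mM, 2768496 reads were deposited and 3.61% (3.58 to 3.63) were repeats. Reads or peaks lay on 16377 scaffolds with 1455732639 bases in total. Unique reads per kb of scaffold were 1.84 and 1.74 in 500 mM and 2.56 and 1.83 in 700 mM, stage 9 first. At this depth a peak held few reads, with a median of 9 and 11 unique reads per peak in 500 mM and 18 and 15 in 700 mM.

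Captured DNA was concentrated in a small part of the genome at both stages, and more so in the gastrula libraries. In 500 mM, the stage 9 list held 82993 peaks covering 58.4 Mb and the stage 12.5 list held 104421 peaks covering 77.0 Mb. In 700 mM, the lists were closer, with 74079 peaks over 105.0 Mb at stage 9 and 72845 peaks over 96.7 Mb at stage 12.5. Peaks of the 500 mM lists were narrower, with medians of 640 and 687 bp, than those of the 700 mM lists, with medians of 1282 and 1207 bp. The share of unique reads inside a library's own peaks was 32.3% (32.2 to 32.3) at stage 9 and 59.2% (59.1 to 59.2) at stage 12.5 in 500 mM. In 700 mM the shares were 47.2% (47.1 to 47.2) and 55.05% (54.99 to 55.11). These shares also move with how much sequence each list covers, so reads were counted over 1 common set of regions. That set joins the peaks of these same libraries, and the stage 12.5, 500 mM list is the longest. It therefore favours places rich in reads of that library. The merged regions of all 4 lists covered 171.6 Mb, or 11.8% of the scaffolds, with a median width of 1060 bp. In 500 mM, reads per kb in them exceeded those outside 7.30-fold at stage 9 and 16.7-fold at stage 12.5. In 700 mM, the excess was 11.0-fold at stage 9 and 15.9-fold at stage 12.5. Per 1000000 unique reads of the library, sequence outside the regions held 0.241 reads per kb at stage 12.5 and 0.394 at stage 9 in 500 mM, and 0.249 and 0.316 in 700 mM. Inside the regions, the same measure was 4.03 at stage 12.5 and 2.88 at stage 9 in 500 mM, and 3.96 and 3.46 in 700 mM. The lists rest on thresholds that are not given in the sources used here, and peaks with 0 unique reads of their own library occurred in both 500 mM lists.

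In the lists as deposited, most blastula peaks were found again in the gastrula, in both fractions. The question was how far the methylated part of the genome is shared between the 2 stages. In 500 mM, 55574 of 82993 stage 9 peaks (67.0%, 66.6 to 67.3) overlapped a stage 12.5 peak, against a mean of 14.4% in random placements. In the other direction, 53870 of 104421 stage 12.5 peaks (51.6%, 51.3 to 51.9) overlapped a stage 9 peak, against 11.3%. In 700 mM, 70.9% (70.6 to 71.2) of stage 9 peaks and 72.2% (71.9 to 72.5) of stage 12.5 peaks overlapped the other list, against 20.4% and 20.7%. Shared bases made up 33.9% of all bases covered by either list in 500 mM and 48.6% in 700 mM, against 3.52% and 6.18% at random. Peaks found at a single stage were still rich in reads at the other. The 50551 stage 12.5 peaks in 500 mM with no stage 9 partner held 28.1 times the reads per kb outside regions at stage 12.5, and 6.38 times at stage 9. The 27419 stage 9 peaks in 500 mM with no stage 12.5 partner held 12.8 times at stage 9 and 9.15 times at stage 12.5. Each fold is over that library's own outside density, which was higher at stage 9, so the folds do not give the change between stages. In unique reads, those stage 12.5 peaks held 547880 at stage 12.5 and 215323 at stage 9. The stage 9 peaks held 226406 at stage 9 and 93532 at stage 12.5. In 700 mM, the 20247 stage 12.5 peaks without a partner held 18.6 times at stage 12.5 and 7.18 times at stage 9. Among the stage 9 peaks in 500 mM without a partner, 7.60% had 0 reads in the stage 12.5 library. When overlap had to span at least 50% of both peaks, 53.5% of stage 9 peaks in 500 mM and 64.9% of stage 12.5 peaks in 700 mM were shared. The 500 mM lists differ in length, and with equal numbers of the peaks richest in reads, a choice made after the data were seen, 56.5% of stage 9 peaks in 500 mM were overlapped with as many peaks as the shorter list and 37.5%, under 50%, with 50% as many.

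**Figure D1:**
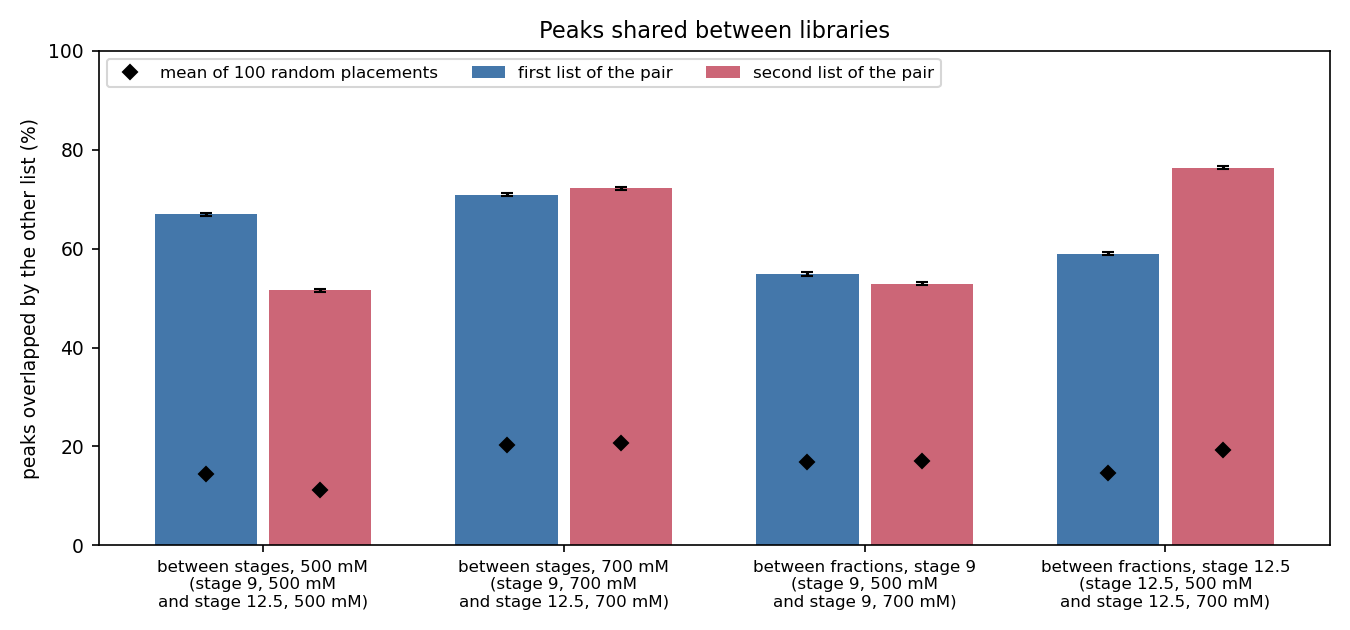
Percentage of peaks overlapped by at least 1 base of the other list, for each of the 4 pairs of libraries (bars, with exact 95% intervals covering counting error), and the mean of 100 random placements (diamonds). Every bar lies above its diamond, from 51.6% against 11.3% to 76.3% against 19.3%.

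The fractions shared fewer peaks at the blastula stage than at the gastrula stage. This comparison asked whether DNA released by less and by more salt comes from the same places. At stage 9, 54.9% (54.6 to 55.2) of 500 mM peaks overlapped a 700 mM peak and 52.9% (52.6 to 53.3) of 700 mM peaks overlapped a 500 mM peak, against 16.9% and 17.1% at random. At stage 12.5, the shares were 59.0% (58.7 to 59.3) and 76.3% (76.0 to 76.6), against 14.6% and 19.3%. Shared bases made up 25.3% of the covered bases at stage 9 and 36.1% at stage 12.5. Of the 141246 merged regions, 27466 (19.4%) had a peak in all 4 lists. Regions with a peak in both 500 mM lists alone numbered 11945, and regions with a peak in both 700 mM lists alone numbered 6248. Another 6818 had a peak in both stage 12.5 lists alone and 3271 in both stage 9 lists alone. The stage 12.5, 500 mM list was the longest, which raises the share of 700 mM peaks it can meet, and with equal numbers of the peaks richest in reads, a choice made after the data were seen, the share of 700 mM peaks overlapped was 48.6% at stage 9 and 58.6% at stage 12.5, or 31.0% and 41.4% with 50% as many. With overlap over at least 50% of both peaks, 26.5% of 700 mM peaks were shared at stage 9 and 49.3% at stage 12.5. This rule also depends on peak width, since a narrow peak that lies wholly inside a wide one can fail it. Median widths were 640 bp in 500 mM and 1282 bp in 700 mM at stage 9, and 687 and 1207 bp at stage 12.5. The widths were thus less alike at stage 9, and the values under this rule do not compare the stages.

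**Figure D2:**
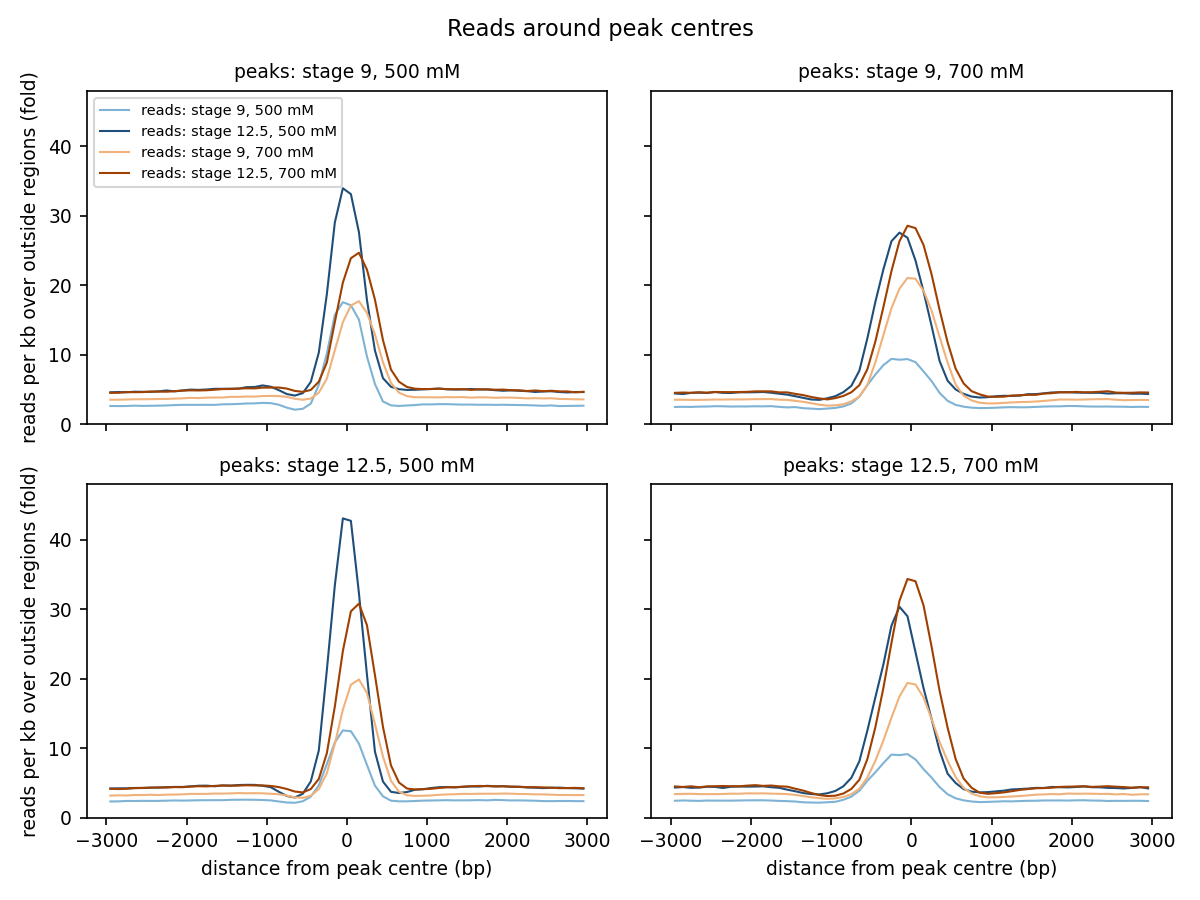
Unique reads per kb around peak centres, in bins of 100 bp out to 3000 bp on either side, as fold over the same library's reads per kb outside the merged regions, for the peaks of each list (panels) and the reads of each library (lines). Stage 12.5 reads rise higher than stage 9 reads of the same fraction in every panel, up to 43.1-fold in 500 mM, and reads of the other fraction lie to one side of the centre, with a centre of mass at 126.6 bp for stage 9 reads of 700 mM around stage 9 peaks of 500 mM.

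In 500 mM, captured regions held more reads in the gastrula than in the blastula library. Over 55266 regions the median log2 ratio of stage 12.5 over stage 9 was 0.583 (0.578 to 0.595), and 77.8% of the regions had a positive ratio. Beyond 2-fold, 15534 regions were higher (28.1%) and 1541 were lower (2.79%), where draws with the same median and no other difference gave 17.9% and 0.22%. Relative to the median, 4757 regions were higher (8.61%) and 5585 were lower (10.1%), against 3.04% and 2.59% in draws. The removed median itself sets the balance of these last numbers. Scaling to reads outside peaks gave 36289 higher and 229 lower, so the size of the imbalance depended on the scaling. With or without the shift, regions differed from one another more than counting allowed, with a standard deviation of log2 ratios of 0.78 against 0.51 in draws. The single libraries do not tell a change in the embryos from a change in how sharply a capture separated DNA.

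In 700 mM, the shift between stages was smaller and in the same direction. Over 79443 regions the median log2 ratio was 0.235 (0.226 to 0.238), and 65.3% of the regions had a positive ratio. Beyond 2-fold, 6722 regions were higher at stage 12.5 (8.46%) and 2464 were lower (3.102%), where draws gave 5.85% and 0.94%. Relative to the median, 3098 regions were higher (3.90%) and 4460 were lower (5.61%), against 2.25% and 2.40% in draws. Scaling to reads outside peaks gave 17506 higher and 892 lower. The standard deviation of log2 ratios was 0.61 against 0.49 in draws. The difference in shift between the fractions was not tested, since each rests on 1 pair of libraries.

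Regions differed widely in how their reads divided between the fractions, to a like extent at both stages once the median was removed. At stage 9, the median log2 ratio of 700 mM over 500 mM was 0.384 (0.379 to 0.396) over 67831 regions, with 15242 regions over 2-fold higher in 700 mM (22.5%, against 10.1% in draws) and 3680 lower (5.42%, against 0.54%). Relative to that median the numbers were 7868 (11.6%) and 7054 (10.4%), and scaling to reads outside peaks gave 24177 and 1900. At stage 12.5, the median was 0.031 (0.031 to 0.039) over 67236 regions, with 7921 higher in 700 mM (11.8%, against 2.93% in draws) and 7000 lower (10.4%, against 2.04%). Relative to that median the numbers were 7140 (10.6%) and 7461 (11.1%). The sign of this small median changed with the settings, reaching -0.08 with a minimum of 10 reads. At both stages the spread of ratios was far above counting error, with a standard deviation of 0.89 against 0.52 in draws at stage 9 and 0.89 against 0.49 at stage 12.5. Scaffold 906 from 18781 to 19762 stood on the 700 mM side at both stages, 5.42-fold (3.67 to 8.28) at stage 9 and 5.77-fold (4.06 to 8.40) at stage 12.5. Scaffold 1804 from 24733 to 25641 was also higher in 700 mM, 4.69-fold (3.50 to 6.41) and 2.55-fold (2.07 to 3.15). Scaffold 1475 from 53205 to 53805 stood on the 500 mM side, with reads 4.98-fold (2.09 to 13.6) higher in 500 mM at stage 9 and 10.7-fold (5.17 to 25.6) at stage 12.5. The fractions also differ in how their files were made, as interval length and strand show.

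The stage ratios of the 2 fractions went together, weakly, across regions. Among 45071 regions with enough reads in both, Spearman's rho was 0.21 and Pearson's r 0.23, where the highest rho in draws was 0.005. These regions are not independent replicates, and both fractions of a stage were eluted from captured DNA in successive steps, so they do not repeat the stage comparison. Counting error lowers such a correlation. Over the 55266 regions measured in 500 mM, the ratios had a standard deviation of 0.78, against 0.51 in draws. Over the 79443 measured in 700 mM, it was 0.61 against 0.49. It was not computed for the 45071 regions alone. The low rho therefore does not measure how far the fractions would agree at greater depth. Regions over 2-fold higher at stage 12.5 in both fractions numbered 997, against 769.5 shared by independent lists of these lengths and at most 411 in draws. Regions over 2-fold lower in both numbered 155, against 23.3 for independent lists and at most 3 in draws. Relative to the medians, 140 regions were higher in both (99.0 for independent lists, at most 36 in draws) and 645 were lower in both (179.2, at most 29). Relative to the medians the order of the 2 directions turned, but the removed medians themselves set that balance. Under scaling to reads outside peaks there were 6259 higher and 15 lower. With at least 50 reads in each fraction, 39 were higher in both and 8 were lower.

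**Figure D3:**
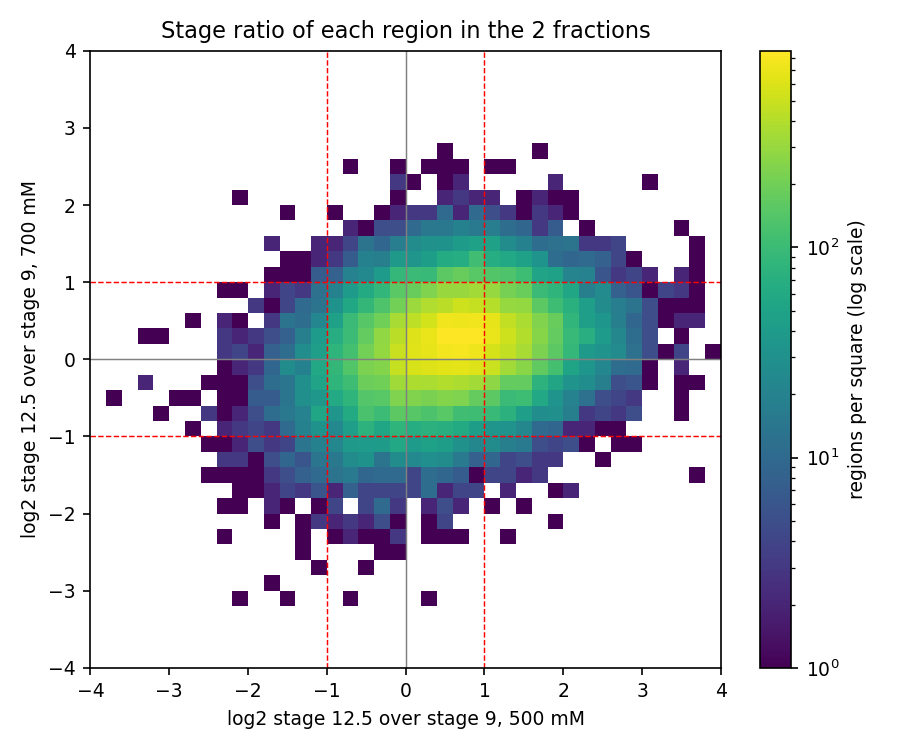
Log2 ratio of stage 12.5 over stage 9 in 500 mM (horizontal) and in 700 mM (vertical) for 45065 regions with at least 20 unique reads in each fraction, with 6 more beyond the axes; the colour gives the number of regions per square on a log scale, and dashed lines mark 2-fold. The cloud is centred at 0.61 and 0.21 and leans weakly upward, with a Spearman's rho of 0.21.

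The 155 regions that were lower in both fractions held most of their reads at stage 9, as the rule that chose them requires. Together they held 3832 reads at stage 9 and 1267 at stage 12.5 in 500 mM, and 4430 and 1118 in 700 mM. At stage 9, 96.1% of them were in the 500 mM peak list and 97.4% in the 700 mM list. At stage 12.5 these shares were 25.8% and 3.23%. Over all tested regions, the shares were 77.2% and 88.9% at stage 9 and 95.3% and 85.95% at stage 12.5, 500 mM first. Choice by a fall in reads favours the stage 9 lists. The region on scaffold 434 from 65567 to 67720 had 31 reads at stage 9 and 5 at stage 12.5 in 500 mM, 5.86-fold lower (2.26 to 19.3), and 35 and 4 in 700 mM, 6.26-fold lower (2.24 to 24.2). On scaffold 449 from 656060 to 658134, reads went from 25 to 4 and from 26 to 4, 5.91-fold (2.04 to 23.4) and 4.65-fold (1.61 to 18.3) lower. On scaffold 102 from 1403686 to 1405828, they went from 23 to 6 and from 26 to 4, 3.62-fold (1.44 to 10.9) and 4.65-fold (1.61 to 18.3) lower. On scaffold 751 from 372759 to 374301, they went from 19 to 4 and from 21 to 4, 4.49-fold (1.49 to 18.1) and 3.76-fold (1.27 to 15.1) lower. Scaffold 398 from 1015993 to 1017760 went from 17 to 3 reads in 500 mM, a ratio of 0.187 (0.035 to 0.645), and from 24 to 1 in 700 mM, a ratio of 0.058 (0.0014 to 0.357). The remaining 3 were on scaffold 201 from 434616 to 436612, scaffold 507 from 134072 to 135714, and scaffold 32 from 3817024 to 3818449, all with ratios between 0.187 and 0.249. With 3 or 4 reads left at stage 12.5, the intervals of these ratios ran from 0.035 at the lowest to 0.853 at the highest. All 8 were in both stage 9 peak lists and in neither stage 12.5 list.

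The 997 regions that were higher in both fractions went from 7851 to 21943 reads in 500 mM and from 14535 to 25010 in 700 mM, on 531 scaffolds. Of these regions, 44.1% were in the stage 9, 500 mM list and 42.1% in the stage 9, 700 mM list, against 77.2% and 88.9% of all tested regions. Over 99% were in each stage 12.5 list, against 95.3% of all tested regions in 500 mM and 85.95% in 700 mM. Choice by a rise in reads favours the stage 12.5 lists. The region on scaffold 334 from 1268226 to 1269200 went from 2 to 22 reads in 500 mM, a ratio of 11.6 (2.86 to 102.1), and from 5 to 19 in 700 mM, 5.31-fold higher (1.92 to 18.2). On scaffold 35 from 297504 to 299200, reads went from 5 to 22 and from 8 to 25, 4.65-fold (1.72 to 15.7) and 4.37-fold (1.91 to 11.2) higher. On scaffold 124 from 988203 to 989154, they went from 5 to 19 and from 17 to 44, 4.02-fold (1.45 to 13.8) and 3.62-fold (2.03 to 6.75) higher. On scaffold 245 from 524356 to 525273, they went from 6 to 27 and from 7 to 19, 4.76-fold (1.93 to 14.1) and 3.79-fold (1.53 to 10.7) higher. The other 4 lay on scaffold 456 from 271694 to 272389, scaffold 42 from 2647668 to 2648857, scaffold 154 from 1371075 to 1372200, and scaffold 426 from 290394 to 291557. Their ratios ran from 4.02 to 4.50 in 500 mM and from 4.19 to 5.94 in 700 mM. The named regions are the extremes of 45071 and rest on few reads, so their ratios lie farther from 1 than a second set of libraries would be likely to give. A minimum of 50 reads in each fraction would have left none of these 16 regions, since all of them had fewer in 500 mM.

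**Figure D4:**
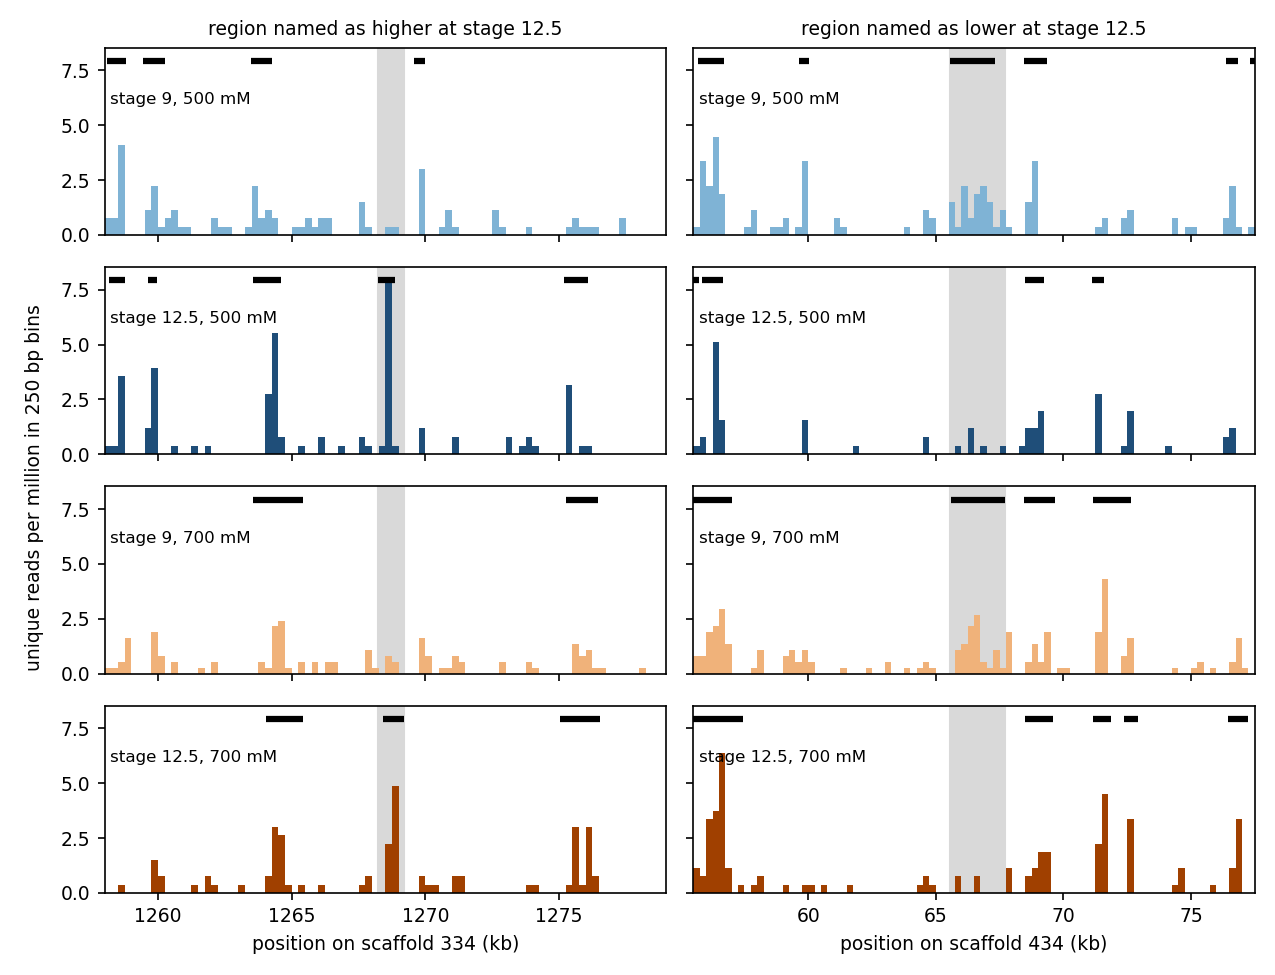
Unique reads per 1000000 unique reads of the library in bins of 250 bp around the first named region of each direction, on scaffold 334 (left) and scaffold 434 (right), for the 4 libraries (rows); grey marks the named region and black bars the peaks of that library's list. In the grey span on scaffold 334, reads go from 2 to 22 in 500 mM and from 5 to 19 in 700 mM, and in that on scaffold 434 from 31 to 5 and from 35 to 4.

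On scaffolds of at least 10000 bp, the regions with the most reads per kb went different ways between stages. The region on scaffold 43 from 2618835 to 2621053 led these in the stage 9, 500 mM library with 193.8 reads per kb. It went from 430 to 147 reads in 500 mM, 2.77-fold lower at stage 12.5 (2.29 to 3.36), and from 375 to 112 in 700 mM, 2.40-fold lower (1.93 to 2.98). Scaffold 96 from 174587 to 176692 was also lower, 2.39-fold (1.91 to 3.02) and 1.80-fold (1.5 to 2.17). Scaffold 1804 from 24733 to 25641, first among these in both 700 mM libraries with 374.0 and 375.1 reads per kb, was higher at stage 12.5, 2.58-fold (1.86 to 3.64) in 500 mM and 1.40-fold (1.203 to 1.63) in 700 mM. Scaffold 1475 from 53205 to 53805 was 3.43-fold higher (2.17 to 5.60) in 500 mM, and its 7 and 8 reads in 700 mM could not show a difference. Scaffold 981 from 145816 to 146496 had 108 and 107 reads in 500 mM, a ratio of 1.05 (0.794 to 1.38), and 111 at both stages in 700 mM, a ratio of 1.40 (1.06 to 1.83). Scaffold 906 from 18781 to 19762 had ratios of 1.35 (0.807 to 2.27) and 1.44 (1.19 to 1.74). Without a library of uncaptured DNA, the copy number of these regions was not measured.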

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

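No test of an explanation was made in this part. Among the 45071 regions measured in both fractions, 125 were over 2-fold higher at stage 12.5 in 500 mM and over 2-fold lower in 700 mM. Another 20 were lower in 500 mM and higher in 700 mM. These regions drew attention because the 2 fractions moved in opposite directions between the same stages, and the difference was not tested for want of replicates. Independent lists of the same lengths would share 314 and 57.2 such regions, so opposite moves were fewer than independent lists give. Draws with no difference but the medians gave at most 85 in both directions together. The strongest of the 125, named after its values were seen, was on scaffold 283 from 1287847 to 1289328. It had 6 and 23 reads in 500 mM, 4.05-fold higher at stage 12.5 (1.60 to 12.2), and 28 and 4 in 700 mM, 5.01-fold lower (1.75 to 19.6). The strongest of the 20 was on scaffold 702 from 350775 to 352455. It had 21 and 4 reads in 500 mM, 4.96-fold lower (1.68 to 19.9), and 9 and 30 in 700 mM, 4.66-fold higher (2.16 to 11.2).

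The strand column of the 700 mM reads, used in the report to count unique reads and, in an alternative, to place reads, carried a signal. Starts of minus strand intervals in 700 mM met starts of 500 mM intervals most often at an offset of 164 bp, and plus strand starts did so at -1 bp, in all 4 pairings of libraries and over 601 offsets tried. For the stage 9 libraries, 38723 minus strand reads met a 500 mM start at that offset, where the median over offsets was 14400. Around stage 9 peak centres of 500 mM, the centre of mass of stage 9 reads of 700 mM lay at 126.6 bp, and that of 500 mM reads at -2.31 bp. Minus strand reads of 700 mM thus appear to lie further up the scaffold than their 500 mM counterparts, by construction of the files. Placing 700 mM reads 150 bp downstream of their inferred ends left the median log2 ratio between stages in 700 mM and that between fractions at stage 9 within their intervals, and moved the median between fractions at stage 12.5 to 0.023, outside its interval of 0.031 to 0.039.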

How the results depend on the processing

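Equal numbers of top peaks, the pooled median of reads per kb, 1 read per start, the removal of 12 scaffolds and the limit to scaffolds of at least 10000 bp were alternatives chosen after the data had been seen, and the others were planned. No paired analysis was possible within any of the 4 comparisons because each had 1 library per group. Analyses over all 4 libraries, with the stages as 2 pairs of fractions or with stage and fraction in an additive model, could have been made and were not run, and no library could be left out of a group of 1. Alternatives that needed peak scores or gene positions were not run. The placement 150 bp downstream had no strand to work with in 500 mM, and all deposited reads equal the unique reads there. Library depth with all deposited reads and peak numbers after merging within 500 bp stayed within 1.5 times. The 8 higher and 8 lower named regions kept their direction in the 4 settings that can change their ratios in 500 mM, no nearer to 0 than 1.23 and -0.99 in log2, and in 7 such settings in 700 mM, no nearer than 1.36 and -0.98. Minimums of reads and limits to scaffolds cannot change these ratios, and with a minimum of 50 reads none of the 16 was left in 500 mM. In each setting given below the cause of a move was not tested unless the setting itself sets it. Depth limited single regions, since 20 reads split between 2 libraries leave intervals of several fold.

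Overlap percentages, in the order of stages in 500 mM, stages in 700 mM, fractions at stage 9 and fractions at stage 12.5, are those of the shorter list's peaks. They were 53.5%, 64.9%, 26.5% and 49.3% when at least 50% of both peaks had to overlap, and 73.3%, 75.9%, 59.2% and 80.1% with peaks widened by 500 bp. They were 56.5%, 71.4%, 48.6% and 58.6% with as many top peaks from both lists, and 37.5%, 58.3%, 31.0% and 41.4% with 50% as many. All of these lay above the random means of the full lists, which were made with unwidened peaks. Widening raises overlap at random too, so those means are no baseline for the widened peaks. Between fractions, the values under the 50% rule also depend on peak width, which differed between the lists, and do not compare the stages. Peaks with at least the pooled median of reads per kb numbered 34004 and 66615 in 500 mM and 37034 and 29639 in 700 mM, stage 9 first. In 700 mM this put stage 12.5 further below stage 9 than the full lists did. This limit took reads per kb with no scaling to library totals. The 700 mM libraries held 3730584 unique reads at stage 9 and 2668634 at stage 12.5. A deeper library passes such a limit more easily, so these numbers do not compare the stages.

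Median log2 ratios are given in the same order. They were 1.29, 0.57, 0.70 and -0.020 when scaled to reads outside peaks, and 0.000 in all 4 by construction when scaled by the median. A pseudocount of 5 gave 0.48, 0.27, 0.22 and 0.011, a minimum of 10 reads 0.50, 0.22, 0.23 and -0.076, and a minimum of 50 reads 0.64, 0.24, 0.48 and 0.081. Windows of 2000 bp gave 0.50, 0.20, 0.23 and -0.006. Thinning gave 0.22, 0.38 and 0.000 in the last 3, while stages in 500 mM stayed at 0.585. All deposited reads gave 0.40 between fractions at stage 9 and 0.041 at stage 12.5, and 1 read per start gave 0.38 at stage 9. Placement 150 bp downstream gave 0.023 between fractions at stage 12.5. The medians between stages and between fractions at stage 9 were thus positive in all settings except the centred one, and the median between fractions at stage 12.5 had no stable sign.

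Spearman's rho of the stage ratios was 0.22 with a minimum of 10 reads, 0.26 with 50 reads and 0.19 after thinning, and between 0.207 and 0.213 in the other settings. Regions over 2-fold higher and lower in both fractions numbered 6259 and 15 when scaled to reads outside peaks, 140 and 645 relative to the medians, 442 and 27 with a pseudocount of 5, 3089 and 1031 with a minimum of 10 reads, and 39 and 8 with 50 reads. Thinning gave 836 and 79. Higher regions outnumbered lower ones in every setting but the centred one, where the removed median sets the balance.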

Other observations

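All tests of explanations in this part, and the choice of the scaffolds, windows and classes named in it, were made after the results they concern had been seen. The test of an even background replaced an earlier one on merged regions, which could not bear on the shift because the mixture had been fitted to it. The gain of 500 mM reads at stage 12.5 was graded by how much DNA of the same place eluted at 700 mM. Windows of 2000 bp with at least 20 unique reads in 700 mM, chosen without regard to 500 mM reads, were divided into 4 classes by those reads. From the lowest class to the highest, the log2 stage ratio in 500 mM was 0.26, 0.37, 0.49 and 0.71, with counting intervals of 0.249 to 0.266 in the lowest and 0.707 to 0.719 in the highest. In the same windows the 700 mM ratio was 0.09, 0.13, 0.18 and 0.27. A different set of windows, those with at least 20 unique reads in 500 mM, was classed by their 500 mM reads. There the 700 mM ratio went from 0.13 (0.126 to 0.142) to 0.22 (0.211 to 0.223). Over merged regions classed by the other fraction, the 500 mM ratio was 0.01, 0.33, 0.52 and 0.78, while the 700 mM ratio was 0.20, 0.17, 0.19 and 0.21, with no steady rise.

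Stage ratios of the 2 fractions also went together across whole scaffolds. Over the 447 scaffolds of at least 1000000 bp, the stage ratios of all unique reads in 500 mM and in 700 mM had a Spearman's rho of 0.70 across scaffolds, where the highest in 100 draws without scaffold differences was 0.19. For reads in merged regions rho was 0.59 (at most 0.12 in draws), and for reads outside them 0.46 (at most 0.14). In both fractions scaled reads rose inside merged regions and fell outside them. A scaffold with a larger share of such regions would thus rise in both, and the draws held no such difference. The rho of all unique reads therefore does not show a stage difference of scaffolds. The other 2 values hold regions and outside sequence apart, but not regions of different read density. Scaffolds are not independent replicates, and both fractions of a stage share embryos and capture. Among 91 regions with at least 100 unique reads at stage 9 in both fractions, 57 had positive stage ratios in both and 15 had negative ones, in a set whose choice by stage 9 reads favours falls. In 500 mM, 7 of the 91 were over 2-fold higher and 6 over 2-fold lower. In 700 mM, 0 were over 2-fold higher and 1 was lower, the region on scaffold 43 from 2618835 to 2621053. On the short scaffold 19023, of 3231 bp, the region from 982 to 2649 went from 145 to 28 reads in 500 mM, 4.90-fold lower (3.25 to 7.62), and from 115 to 42 in 700 mM, 1.96-fold lower (1.36 to 2.86). On scaffold 18215, of 3599 bp, the region from 159 to 1975 went from 617 to 255 and from 966 to 370 reads. The others over 2-fold lower in 500 mM were on scaffolds 43, 96, 18302, of 2991 bp, and 18005, of 3421 bp. At stage 9 in 500 mM these 6 regions held 86.9 to 339.6 reads per kb, where merged regions held 7.71. The 4 libraries include none of uncaptured DNA, so a difference in copy number of such sequence was not tested.

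The first pattern weighed is the shift of captured regions toward more 500 mM reads at stage 12.5. A background spread evenly over the genome in the stage 9, 500 mM library was fitted as a mixture with the stage 12.5 profile and took a share of 39.9% of reads. It predicted a rise of 0.20 across the 4 classes of windows where 0.46 was observed, an excess of 0.250, which argues against an even background as the whole cause and leaves it open as a part. A better separation of bound from unbound DNA in the stage 12.5 preparation may be the cause, as may a gain of methylation in the embryos, and these cannot be told apart with 1 library per group: the contrast of regions over outside sequence was 2.29 times as high at stage 12.5 in 500 mM and 1.45 times in 700 mM. That contrast was taken over the peaks of these same libraries, of which the stage 12.5, 500 mM list was the longest, and may be raised by this choice.

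The second pattern is the set of 155 regions lower at stage 12.5 in both fractions. Its size depended on the processing, from 8 to 1031 regions over 12 settings. Relative to sequence outside merged regions, reads per kb in the 155 went from 12.8-fold at stage 9 to 7.33-fold at stage 12.5 in 500 mM. In 700 mM they went from 13.3-fold to 5.93-fold. A copy number difference of long stretches would have lowered the flanks too, but the flanks of 20000 bp had summed log2 ratios of -0.04 in 500 mM and -0.072 in 700 mM. A deletion of the whole region in all stage 12.5 embryos would have left most regions without reads, whereas 100% of them had at least 1 read at stage 12.5, with a median of 12 over both libraries, and a deletion within a region stays open. A difference between the embryo batches or captures of the 2 stages, shared by both elutions, cannot be told apart from a loss of methylation between blastula and gastrula with 1 capture per stage: the 155 regions exceed counting error, with at most 3 in draws, but the draws hold no variation between preparations. A loss of methylation was not tested and stays a hypothesis, which bisulfite sequencing of these regions in further embryo batches would test, and a sequence difference carried by some of the embryos also stays open.

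The third pattern is an excess of 700 mM over 500 mM reads on 12 of 2161 scaffolds with at least 200 reads. Scaled 700 mM reads exceeded 500 mM reads at least 4-fold there. On scaffold 1099, of 313420 bp, 500 mM reads numbered 84 and 157 and 700 mM reads 1139 and 2556, stage 9 first, and on scaffold 7921, of 86920 bp, they numbered 28 and 39 and 279 and 666. Repeated positions do not account for the excess on the 12 scaffolds, since all deposited reads were 1.41 times the unique reads there (4.92 times on scaffold 7091) and the excess is in unique reads. One added source of DNA in the 700 mM libraries behind all 12 scaffolds would give them a single stage ratio. Their 700 mM counts were heterogeneous, with a chi-square over its degrees of freedom of 22.75. The 6 scaffolds with a stage fold over 2 ranged from 2.95 to 3.39 and the other 6 from 1.23 to 1.67, a division made on that ratio itself. Among the first 6, the chi-square over its degrees of freedom was 0.285, a value that the division itself lowers. A single source for those 6 therefore stays open, as does more than 1 source, or sequence that elutes late for its own reasons. No biological explanation was tested.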
